A study of Mus musculus with 12 samples.

How the data were processed

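RNA was measured by sequencing in germ cells sorted from single female mouse embryos at embryonic day 13.5. All embryos were Gulo-/- on a C57BL/6 background. Gulo encodes the last enzyme of vitamin C synthesis, so such animals take vitamin C from the diet only. The labels assign 6 embryos to mothers supplied with vitamin C and 6 to mothers from which it was withdrawn. Per the labels' protocols, cells positive for Oct4 were sorted, total RNA was extracted with a column kit for small samples, and libraries were made with a SMART-based kit.

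The authors deposited a table of normalized log2 expression values with 12516 gene symbols and 1 column for each of the 12 embryos. Per the submitters' processing notes, the tools were Trim Galore 0.4.0, FastQC, TopHat2 2.0.13 and DESeq2 1.10.1, with genome build mm9. The notes used here give no role or order for these tools. The annotation, the counting tool, the filter on genes and the exact log2 transformation are not given in the sources used here. Every value within a library was distinct down to the lowest, and genes with low values varied little between embryos, as values do after a log transformation that shrinks poorly covered genes. Whole reads could not be recovered from such values, so the sequencing depth of each embryo is unknown and no count test was run. If the scale is of that kind, fold changes of genes with low values are understated. No interval for counting error is given.

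Genes were kept where the mean deposited value over the 12 libraries was at least log2 of 10, or 3.32, which left 12432 genes and dropped 84. Withdrawn embryos were compared with supplied embryos with limma 3.58.1 in R 4.3.3, by a linear model with moderated variances that follow a trend on expression. The test was two-sided, with Benjamini-Hochberg adjustment over all genes kept, and genes were called at an adjusted p below 0.05. The log2 fold change is the withdrawn mean minus the supplied mean, and its standard error (SE) is the moderated one. Adjusted p values of single genes come from this limma fit unless another test is named.

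Before the data were examined, 27 gene lists, the tests and the rule for named genes were fixed. Each list was counted over all genes and adjusted over the list alone. The 24 lists with at least 3 kept members were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Fry asks whether the genes of a list move on balance one way and does not compare them with other genes. The mean value of a list per embryo was also compared by an exact two-sided permutation test over all 924 arrangements of the embryos, whose smallest p is 0.00216. Its p values are printed without adjustment over the lists unless an adjusted one is named. The genes named are the 12 with the largest fold change in each direction among those called and with at least 5 of the 6 withdrawn embryos beyond the supplied mean, up to 4 members of each list with the smallest p, and a short set named in advance (Gulo, Tet1, Tet2, Tet3, Dnmt1, Uhrf1, Stra8, Dazl, Ddx4, Sycp3, Pou5f1, Kit, Xist and Ddx3y). Predicted genes and near-identical copies were counted but named only from the lists or the set. Further called list members given as examples, and all genes in the closing observations, were chosen after their values were seen. Gulo and Ddx3y are not among the listed symbols. A result for a member of the retinoic acid and BMP list is not reported here. Older symbols were matched through the reference's synonyms. An alias written in advance for Majin belonged to another gene and was replaced by that match. The reference annotation was of build GRCm38, not mm9, so it served only for names, chromosomes, transcript length and GC content, and no coordinates are given.

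The sample titles carry a number from 1 to 4 that occurs in both groups, and 4 combinations of number and diet hold 2 embryos each. The labels do not say whether embryos that share a combination are siblings. The series text calls the embryos biological replicates, and p values here treat them as independent. If siblings share a mother, those p values are too small, so fits with such embryos tied by a random effect (statmod 1.5.0) or averaged were also run. Other alternatives changed the filter, the scaling, the variance model, the weights, the threshold and the test. Further ones added a covariate of somatic marker genes or left out each embryo in turn. Removal of the transcript length and GC trend and leaving out all embryos of a title number were added after the data had been seen.

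The fit was tested on simulated data for the comparison of withdrawn with supplied embryos, with 12432 genes of which 200 were changed. It recovered 100% of genes changed by a log2 fold change of 1 and 96% of those changed by 0.5, and 6.22% of its calls were false. With no change simulated, 0 genes and 0 lists were called. Noise was drawn independently for each gene and embryo. The simulation therefore could not show false calls that come from correlated genes, siblings or outlying embryos. For the meiosis list the estimated correlation was 0.396. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.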

Results

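Germ cells of 12 female Gulo-/- mouse embryos at embryonic day 13.5 were profiled, 6 from mothers supplied with vitamin C and 6 from mothers withdrawn from it during gestation. At this age female germ cells pass from mitotic proliferation to meiosis. The comparison asks how the mother's vitamin C affects expression in the embryonic germline. Values are normalized log2 expression per gene and embryo, and the depth of each library is unknown. Correlations between libraries across genes ranged from 0.986 to 0.999.

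In withdrawn embryos, 16 of 36 genes of meiosis and 12 of 26 of germline genome defence were lower and 16 of 26 genes of germ cell pluripotency were higher. These 3 lists passed camera, but each had an adjusted p = 0.237 with an estimated correlation. The largest decreases were in Stra8, Trank1, Meioc, Sycp1 and Rec8, and the largest increases in Hmgn5, Apoe, L1td1 and Sox15. Of 12432 genes tested, 1737 were called, 773 higher and 964 lower in withdrawn embryos. Most changes were small. The median absolute log2 fold change of the called genes was 0.28, 107 of them reached 0.5 and 6 reached 1. The 2 groups did not overlap for 558 genes, or 4.49% of those tested, where chance gives 0.216% on average over all arrangements. That average takes the embryos as independent, and with correlated genes a single arrangement can lie far from it. The first principal component held 45.5% of the variance and differed between the diets (exact permutation p = 0.00433). Supplied replicate 4 lay at 1.54 on it, within the withdrawn range of 1.27 to 23.2, and the other supplied embryos lay between -18.3 and -6.56.

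The number of called genes depended on how embryos were treated. It was 886 with embryos sharing a title number and diet tied by a random effect, 298 with such embryos averaged and 91 with the mean of somatic marker genes as a covariate. An exact permutation test per gene called 558, which were the genes whose groups do not overlap. The limma count was 49 without the 4 embryos of title number 4 and 729 without those of title number 1. It was 808 without supplied replicate 5 and 1133 without supplied replicate 6. All 1737 genes kept their direction in each of these fits. Lower genes were the majority of those called in the reported fit, but with median centring 904 were higher and 795 lower, and with the length and GC trend removed 924 were higher and 806 lower.

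**Figure D1:**
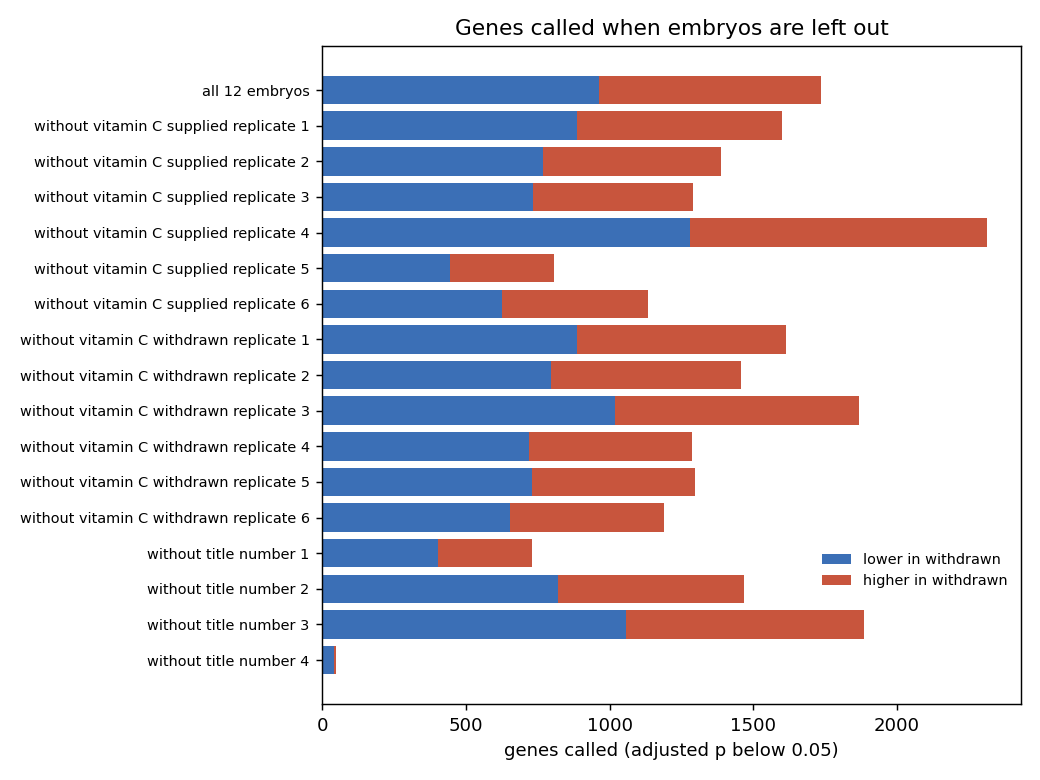
Number of genes called by limma at an adjusted p below 0.05 (horizontal axis) with all 12 embryos and without each embryo or each title number. Blue bars are genes lower and red bars genes higher in withdrawn embryos; the count ranges from 49 without title number 4 to 2315 without supplied replicate 4.

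Stra8, the retinoic acid target needed for meiotic entry, had a mean of 10.35 ± 1.02 (SD, n = 6) in supplied and 8.57 ± 0.73 in withdrawn embryos, a log2 fold change of -1.77 (SE 0.35, adjusted p = 0.00340), which is 3.42-fold lower. Sycp1, a component of the synaptonemal complex, went from 10.26 ± 0.35 to 9.03 ± 0.27, a log2 fold change of -1.23 (SE 0.13, adjusted p = 3.81e-05), with no overlap between the groups. The listed pseudogene Sycp1-ps1 moved by -0.64, and reads may be divided between both copies. Rec8, a meiotic cohesin, changed by -1.15 (SE 0.18, adjusted p = 0.00162). Its cohesin partner Stag3 changed by -0.42 (SE 0.07, adjusted p = 0.00219). Further called members were Meioc (-1.32), which maintains the meiotic programme, the cohesin subunit Smc1b (-0.68), the recombinase Dmc1 (-0.47) and Sycp2 (-0.48). Sycp3 was at -0.26 and did not pass (adjusted p = 0.113).

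Of 36 meiosis genes kept, 16 were lower and 0 higher, and 26 were lower adjusted over the list alone. Their median log2 fold change was -0.22, and 33 of 36 were negative. The mean of the list per embryo was 7.86 ± 0.19 in supplied and 7.52 ± 0.10 in withdrawn embryos (SD, n = 6 each, exact permutation p = 0.00866). The list passed camera (adjusted p = 5.16e-09) but not with an estimated correlation (adjusted p = 0.237). Without title number 4, 3 members were called, and Stra8 was at -0.99 (adjusted p = 0.151). Stra8 was also not called with the somatic covariate (adjusted p = 0.0669) or by the exact test per gene (adjusted p = 0.0830). The exact test called only the genes whose groups do not overlap, and the groups of Stra8 overlap. Over all alternatives the adjusted p of Stra8 ranged from 9.55e-05 to 0.151. The list itself still passed camera at the preset correlation without title number 4 (median -0.13, adjusted p = 2.84e-06). An estimated correlation was not run there. At the preset correlation camera also passed lists in other splits of the embryos that called 0 genes, so this pass is weak support. Sycp1 was called in all 31 alternatives, with adjusted p values from 1.98e-07 to 0.0482.

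**Figure D2:**
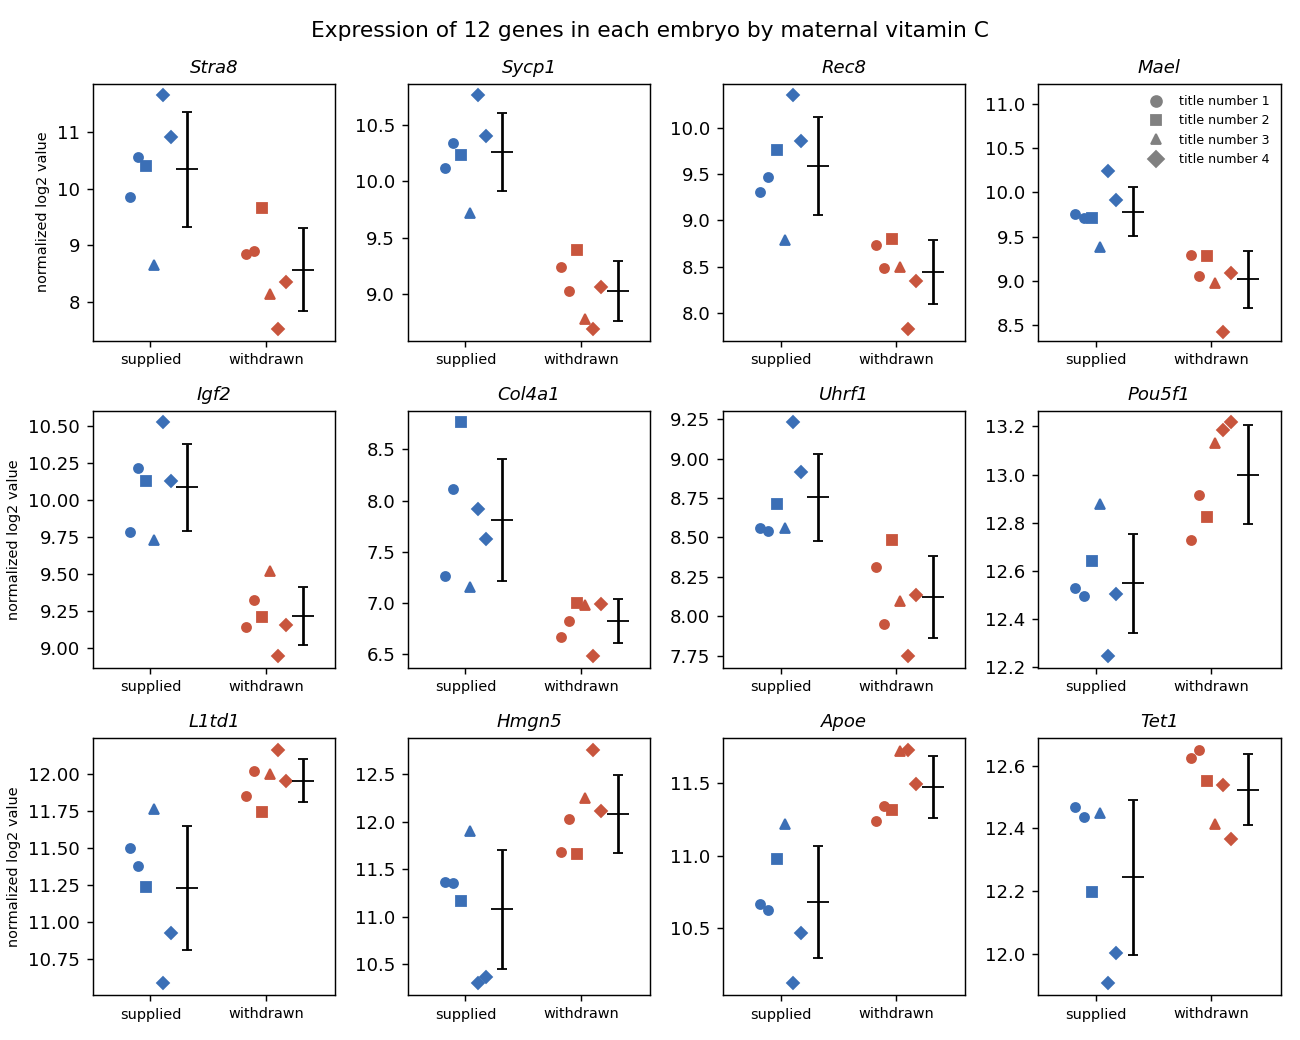
Normalized log2 value (vertical axis) of 12 genes in each embryo, with supplied embryos in blue and withdrawn embryos in red. Marker shapes give the title number, and black bars the mean and SD of the 6 embryos per group; Stra8 averages 10.35 in supplied and 8.57 in withdrawn embryos, and Pou5f1 12.55 and 12.999.

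Among pluripotency genes of germ cells, L1td1, an RNA-binding protein of pluripotent cells, rose from 11.23 ± 0.42 to 11.95 ± 0.14 (log2 fold change 0.72, SE 0.13, adjusted p = 0.00280). The transcription factor Esrrb rose by 0.50 (SE 0.10, adjusted p = 0.00310) and Alpl, the alkaline phosphatase used as a germ cell marker, by 0.30 (SE 0.06, adjusted p = 0.00505). Pou5f1, which encodes Oct4, the factor by which the cells were sorted, rose from 12.55 ± 0.21 to 12.999 ± 0.205 (log2 fold change 0.45, SE 0.09, adjusted p = 0.00505). Dppa4 (0.42), Dppa5a (0.49), Tfap2c (0.39) and Sox2 (0.35) were also called. Of 26 members, 16 were higher and 0 lower, and 19 were higher adjusted over the list alone. The list mean per embryo was 9.86 ± 0.14 in supplied and 10.14 ± 0.10 in withdrawn embryos (exact permutation p = 0.00433). Camera gave an adjusted p of 1.85e-10, and an adjusted p = 0.237 with an estimated correlation. The count of 16 was 9 without supplied replicate 5, 9 without title number 1, 0 without title number 4, 4 with embryos averaged and 1 with the somatic covariate. With that covariate the 32 called members of the meiosis and pluripotency lists kept a median of 0.880 of their fold change (95% bootstrap interval over genes 0.848 to 0.949). Their median SE rose from 0.09 to 0.11. The list still passed camera at the preset correlation without title number 4 (median 0.19, adjusted p = 1.44e-09), where an estimated correlation was not run.

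**Figure D3:**
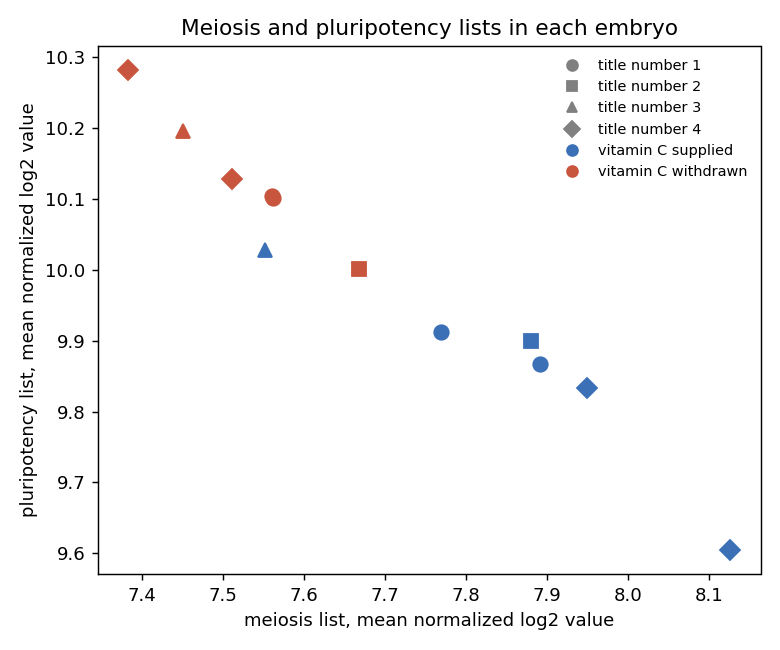
Mean normalized log2 value of the 26 pluripotency genes (vertical axis) against that of the 36 meiosis genes (horizontal axis), 1 point per embryo, blue for supplied and red for withdrawn, with the title number as shape. Supplied embryos average 7.86 on the horizontal axis and withdrawn embryos 7.52; supplied replicate 4 lies at 7.55.

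Most genes on the germline genome defence list act in the piRNA pathway against transposons. Mael fell from 9.78 ± 0.28 to 9.02 ± 0.32 (log2 fold change -0.77, SE 0.13, adjusted p = 0.00209). Tdrd1 changed by -0.66 (SE 0.12), Mov10l1 by -0.47 (SE 0.09) and Asz1 by -0.37 (SE 0.07). The germ cell RNA-binding genes Dazl (-0.43, adjusted p = 0.0212) and Ddx4 (-0.34, adjusted p = 0.0362) were called, and neither was called without title number 4 (-0.27 and -0.19, adjusted p 0.297 and 0.398). Their calls were lost in 12 and 16 of 31 alternatives, with adjusted p values from 0.00377 to 0.297 for Dazl and from 0.0115 to 0.398 for Ddx4. Of 26 members, 12 were lower and 1, Mov10, was higher; adjusted over the list alone, 13 were lower and 1 higher. The list differed in its mean per embryo (exact permutation p = 0.00649) and in camera (adjusted p = 0.000226), and had an adjusted p = 0.237 with an estimated correlation. Its 12 lower members were 7 without supplied replicate 5, 6 without title number 1 and 3 without title number 4.

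Among genes of retinoic acid and BMP signalling, which drive meiotic entry, the receptors Rara (-0.32, SE 0.08), Rxra (-0.39, SE 0.10) and Bmpr1a (-0.36, SE 0.08) and the BMP-induced factor Msx1 (-0.55, SE 0.12) were lower. Of the 20 members of this list, 5 were lower, also adjusted over the list alone. Its camera test gave an adjusted p of 0.0245, and an adjusted p = 0.341 with an estimated correlation; it was lost in 2 of 12 fits that left out 1 embryo. None of the 5 lower members was called by limma without title number 4. Of the 4 oocyte genes kept, Sohlh2 was lower (-0.31, adjusted p = 0.0182), also adjusted over the list alone but not called without supplied replicate 5; Ybx2 (-0.17), Taf4b (-0.09) and Kit (0.14) did not pass, nor did the list (adjusted p = 0.269).

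Genes that set and erase DNA methylation changed in both directions. Uhrf1, which recruits the maintenance methyltransferase to replicated DNA, fell from 8.75 ± 0.27 to 8.12 ± 0.26 (log2 fold change -0.63, SE 0.12, adjusted p = 0.00304), with no overlap between the groups, whereas that methyltransferase, Dnmt1, was at 0.01 (SE 0.06, adjusted p = 0.907). Of the Tet dioxygenases, which oxidize 5-methylcytosine with vitamin C as a cofactor, Tet1 was higher (0.28, SE 0.09, adjusted p = 0.0401), Tet3 was lower (-0.48, SE 0.08, adjusted p = 0.00219) and Tet2 did not pass (0.10, SE 0.09, adjusted p = 0.463). The Tet1 call was lost in 17 of 31 alternatives, which gave adjusted p values from 0.00401 to 0.290. Tet3 had values of 6.47 and 5.99. The repair genes Parp1 (0.30) and Apex1 (0.25) were higher and Dnmt3b (-0.27) lower. In all, 3 of 14 members were higher and 3 lower, also adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.733), with a positive median of 0.05 and a negative mean of -0.03. The 3 higher members were 1 without supplied replicate 3, 5 or 6 or withdrawn replicate 5, and without title number 4 none of the 6 was called by limma.

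Of 32 dioxygenases that use 2-oxoglutarate, 2 were higher and 5 lower (2 and 6 adjusted over the list alone). The histone demethylase genes Phf8 (-0.42, SE 0.11), Phf2 (-0.27, SE 0.07) and Kdm5a (-0.29) and the oxygen sensor Egln1 (-0.27, SE 0.08) were lower, and Kdm3a (0.25, SE 0.06) was higher. The list did not pass camera (adjusted p = 0.101) except with quantile normalization (adjusted p = 0.0363), and its 5 lower members were 1 without supplied replicate 5 and 2 without supplied replicate 6. Of 6 genes of vitamin C transport and synthesis, the transporter gene Slc2a3 rose by 0.43 (SE 0.07, adjusted p = 0.00219) and was the 1 called member, also adjusted over the list alone. Slc23a2, the sodium-dependent transporter, was at 0.21 (adjusted p = 0.135) and Slc2a1 at 0.19 (adjusted p = 0.105). This list passed camera (adjusted p = 0.0242), with an adjusted p = 0.237 with an estimated correlation, and lost that call in 4 of 25 alternatives in all. Slc2a3 was at 0.37 and not called without title number 4 (adjusted p = 0.0530) or with the somatic covariate (adjusted p = 0.0519).

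Of 35 imprinted genes, 4 were lower and 0 higher (3 lower adjusted over the list alone). Igf2, a paternally expressed growth factor, fell from 10.09 ± 0.29 to 9.21 ± 0.19 (log2 fold change -0.87, SE 0.11, adjusted p = 0.000284), was 1.83-fold lower with no overlap between the groups, and was called in all 31 alternatives, with adjusted p values from 1.42e-05 to 0.0482. Gnas (-0.46, SE 0.09) and the cell cycle inhibitor Cdkn1c (-0.47, SE 0.11) were also lower, as was Osbpl5 (-0.08), whose values lay near the lowest of the table and whose call was lost in 25 of 30 alternatives. The list had a camera adjusted p of 0.0534 and passed in 8 of 25 alternatives, among them median centring (adjusted p = 0.0436) and 4 of 12 fits that left out 1 embryo.

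The peroxiredoxins Prdx6 (0.48, SE 0.08, adjusted p = 0.00217) and Prdx1 (0.40, SE 0.08), the metallothionein Mt2 (0.49, SE 0.10) and the ferritin light chain Ftl1 (0.41) were among 9 of 21 oxidative stress genes called higher, with 0 lower, 4 members negative and the same counts adjusted over the list alone. The list mean differed between the diets (exact permutation p = 0.00216, the smallest possible). Camera gave an adjusted p of 0.000349, and an adjusted p = 0.237 with an estimated correlation. Of 31 hypoxia response genes, 6 were higher and 1 lower (8 and 1 adjusted over the list alone), among them the glycolytic Pgam1 (0.31), Pgk1 (0.26) and Eno1 (0.22) and the kinase Pdk1 (0.30). That list had a camera adjusted p of 0.00520, and an adjusted p = 0.237 with an estimated correlation. Of 19 p53 targets, 5 were higher (6 adjusted over the list alone), including Gadd45a (0.41), Bax (0.35), Ccng1 (0.32) and Sesn2 (0.28). Their camera adjusted p was 0.00826, and they had an adjusted p = 0.321 with an estimated correlation. Of 17 genes of the integrated stress response, the amino acid transporter genes Slc3a2 (0.35) and Slc7a5 (0.40) and Sesn2 were higher. Adjusted over the list alone, 4 were higher and 1 lower, and the list did not pass camera (adjusted p = 0.0959) but passed fry (adjusted p = 0.00780). Without supplied replicate 5 the higher members numbered 5 for oxidative stress and 3 for hypoxia, and for hypoxia also 3 without withdrawn replicate 6 and 12 without supplied replicate 4. Without title number 4 they numbered 1 for oxidative stress and 0 for hypoxia and p53.

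Mitotic genes were positive for all 20 members, and 5 were called higher, among them Nusap1 (0.28, SE 0.07), Aurka (0.27), Ccnb1 (0.25) and Ccna2 (0.24); 12 were higher adjusted over the list alone. The call of Ccna2 was lost in 16 of 31 alternatives. The list passed camera (adjusted p = 8.79e-07), with an adjusted p = 0.237 with an estimated correlation, and its 5 called members were 1 without supplied replicate 5, 9 without supplied replicate 1 and 0 without title number 4. Of 25 DNA replication genes, limma called 0, also adjusted over the list alone; 5 had an unadjusted p below 0.05, and the exact test called 0. Mcm2 was at 0.14 and Pola1 at -0.19, and the list had a camera adjusted p of 0.0842, which was 0.0414 without supplied replicate 1 and 0.0367 without withdrawn replicate 4. In cholesterol synthesis, 4 of 22 genes were higher, also adjusted over the list alone, namely Mvd (0.28), Lss (0.23), Sc4mol (0.26) and Fdft1 (0.21); the last 2 calls were each lost in 18 of 31 alternatives. The camera adjusted p was 0.0212, and adjusted p = 0.432 with an estimated correlation. Neither fry (adjusted p = 0.141) nor the exact test of the list mean (exact permutation p = 0.136) passed. Without supplied replicate 5, supplied replicate 6 or withdrawn replicate 6, 0 were called. Camera did not pass in 2 of 12 fits that left out 1 embryo. Of 28 genes of mitochondrial respiration, Atp5a1 (0.21), Cox6c (0.32) and Atp5b (0.17) were higher, also adjusted over the list alone. The camera adjusted p was 0.0242, and adjusted p = 0.457 with an estimated correlation. Fry (adjusted p = 0.177) and the exact test of the list mean (exact permutation p = 0.152) did not pass. These 3 calls were 1 without supplied replicate 1 or withdrawn replicate 6 and 0 with quantile normalization. The camera call was lost in 5 of 12 fits that left out 1 embryo, with adjusted p values up to 0.0837, and with quantile normalization (adjusted p = 0.258).

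**Figure D4:**
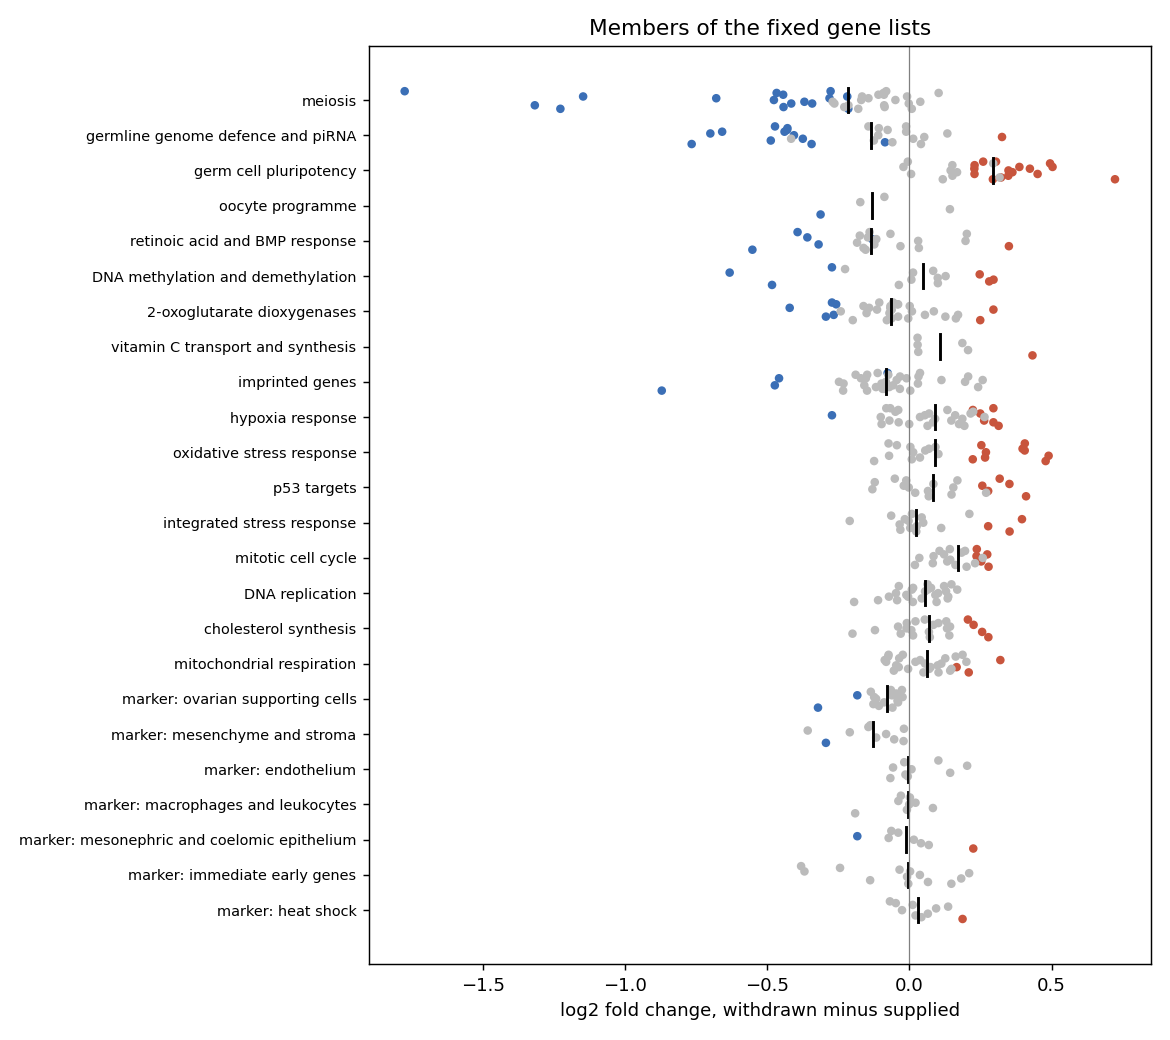
Log2 fold change, withdrawn minus supplied (horizontal axis), of each kept member of the 24 gene lists with a set test. Red points were called higher, blue points lower and grey points were not called at an adjusted p below 0.05, and black ticks are list medians, -0.22 for meiosis and 0.29 for pluripotency.

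Most markers of other gonadal cells had low values, and some moved with the diet. Above the median gene lay 0 of 16 supporting cell, 1 of 10 mesenchymal (Fbln1, 9.63 in supplied and 9.33 in withdrawn embryos), 1 of 9 endothelial (Pecam1, 11.18 and 11.38), 0 of 8 macrophage and 2 of 8 mesonephric markers (Epcam and Cdh1). All 16 markers of ovarian supporting cells were negative. Their list mean was 5.102 ± 0.076 in supplied and 5.004 ± 0.057 in withdrawn embryos (exact permutation p = 0.0325). That test did not pass when adjusted over the lists (adjusted exact permutation p = 0.0618). Of these 16 markers, 2 were called lower, Kitl (-0.32) and Emx2 (-0.18), or 3 adjusted over the list alone. The count of 2 was 0 without supplied replicate 2 or 5 and 1 without withdrawn replicate 1, 3, 5 or 6. All 10 mesenchymal markers were negative as well (5.48 ± 0.13 and 5.34 ± 0.03, exact permutation p = 0.0195, adjusted over the lists 0.0406). Of these, Fbln1 (-0.29) was called, or 6 adjusted over the list alone. That 1 became 5 without supplied replicate 1, 4 without supplied replicate 4, 3 without supplied replicate 6, 2 without withdrawn replicate 4 and 0 without supplied replicate 5 or withdrawn replicate 2. Camera gave adjusted p values of 0.00826 and 0.0203 for these lists, and adjusted p = 0.392 and 0.347 with an estimated correlation. With the mean of the somatic markers as a covariate, 2 meiosis, 3 genome defence, 1 pluripotency and 1 oxidative stress genes were still called. The 32 called meiosis and pluripotency genes then had a median of 0.880 of their fold change (0.848 to 0.949), with a median SE of 0.11 in place of 0.09.

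Of 9 endothelial markers limma called 0, with 2 at an unadjusted p below 0.05, and of 8 macrophage markers 0, with 1; the exact test called 0 in both, and the lists did not pass camera (adjusted p = 0.610 and 0.804). Pecam1 was at 0.20 and Cd68 at -0.19. The endothelial list had a negative median (-0.01) and a positive mean (0.03). Among 8 mesonephric and coelomic markers, Epcam, which germ cells also express, was higher (0.22) and Emx2 lower (camera adjusted p = 0.926; the same 2 adjusted over the list alone); with quantile normalization neither was called, and each call was also lost without some single embryos, among them supplied replicates 3 and 5. The male gonad list had 2 kept genes, Star (-0.03) and Aard (0.09), with 0 called by limma or the exact test and 0 at an unadjusted p below 0.05. None of 8 Y-linked and 12 erythroid symbols was among the listed genes. Xist, which silences an X chromosome in female cells, was at -0.40 (SE 0.18, adjusted p = 0.132). Of 13 immediate early genes limma and the exact test called 0, with 2 at an unadjusted p below 0.05 (Nr4a1 0.15, Jun -0.37). That list and the mesonephric one had a negative median and mean but a positive direction in camera (adjusted p = 0.842 for immediate early genes). Of 10 heat shock genes Hsp90aa1 was higher (0.19), also adjusted over the list alone (camera adjusted p = 0.274), and was not called with quantile normalization or without supplied replicate 3, 5 or 6 or withdrawn replicate 2, 5 or 6.

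Outside the lists, the largest decreases included Trank1 (-1.42, SE 0.22, adjusted p = 0.00151), the collagen IV gene Col4a1 (-0.98, SE 0.18, adjusted p = 0.00288), the cyclin gene Ccnd1 (-0.81, SE 0.15), the transcription factor gene Tcfl5 (-0.78, SE 0.13), the kinase gene Wnk2 (-0.78, SE 0.14), the repressor gene Zfp238, now Zbtb18 (-0.75, SE 0.11), and the receptor gene Gpr125, now Adgra3 (-0.75, SE 0.14). The largest increase was in the nucleosome-binding Hmgn5, from 11.08 ± 0.63 to 12.08 ± 0.41 (log2 fold change 1.01, SE 0.21, adjusted p = 0.00506). Apoe, a lipoprotein component, rose by 0.80 (SE 0.13, adjusted p = 0.00183) and Sox15 by 0.62 (SE 0.11). Next came Amt of the glycine cleavage system (0.61), Csrp2 (0.61), the phosphofructokinase Pfkp (0.60), the scaffold gene Akap12 (0.59), the protease gene St14 (0.57), Tcof1, which acts in ribosomal RNA synthesis (0.55), the kinase gene Mapk4 (0.54) and the lysosomal Ctsa (0.53). All 6 withdrawn embryos lay beyond the supplied mean for each of these genes. Col4a1 was not called with the somatic covariate (-0.56, adjusted p = 0.0562) or without title number 4 (-0.96, adjusted p = 0.0672), and Hmgn5 was at 0.46 without title number 4 (adjusted p = 0.138). Also without title number 4, Apoe was at 0.53 (adjusted p = 0.0530), Ccnd1 at -0.44 (0.108), Gpr125 at -0.43 (0.0775), Sox15 at 0.38 (0.0864), Amt at 0.40 (0.0530), Pfkp at 0.22 (0.243), Akap12 at 0.33 (0.0771), St14 at 0.47 (0.0530), Tcof1 at 0.39 (0.0864), Mapk4 at 0.34 (0.171) and Ctsa at 0.31 (0.204). Calls were lost in 4 of 31 alternatives for Pfkp, Ctsa and Mapk4, in 3 for Ccnd1, Gpr125 and Hmgn5, in 2 for Col4a1, Sox15 and Tcof1 and in 1 for Trank1 (exact test, adjusted p = 0.0598).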

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

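Of 120 sets of 6 embryos examined, 16 held an embryo whose gap to its nearest neighbour, as a share of the range of its group, exceeded Dixon's 95% critical value. Chance gives about 1 in 20 for independent sets. These sets were not independent, so the 16 cannot be weighed against that rate. They also included the genes with the largest fold changes, a choice that favours embryos far out in the direction of their group. The embryo was withdrawn replicate 5 in 8 of the 16. Its first principal component was 23.2, against 1.27 to 9.49 in the other withdrawn embryos. Its value was 7.57 for Tcfl5 (others 8.05 to 8.22), 7.83 for Wnk2 (8.69 to 8.79), 8.42 for Mael (8.97 to 9.29), 7.26 for Zfp238 (7.74 to 7.95) and 7.99 for Gpr125 (8.64 to 8.87). These genes were called lower in withdrawn embryos, so it stood farther in the direction of its group. The same held for Csrp2, a gene called higher, at 9.35 (8.55 to 8.76), and for the oxidative stress list, whose mean was 9.57 (9.40 to 9.45). Without this embryo limma called 1297 genes.

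Supplied replicate 4 stood apart for St14, at 9.15 (others 8.67 to 8.83), and for Dazl, at 12.78 (13.19 to 13.35), in both cases toward the withdrawn embryos. Without it 2315 genes were called. Among the list means, withdrawn replicate 1 had 8.23 for p53 targets (others 8.35 to 8.39). Withdrawn replicate 4 had 11.45 for mitotic genes (11.52 to 11.55) and 7.21 for mesonephric and coelomic markers (7.06 to 7.11). Supplied replicate 2 had 5.82 for endothelial markers (5.64 to 5.70) and supplied replicate 3 had 4.74 for macrophage markers (4.52 to 4.57). Withdrawn replicate 6 had 7.36 for immediate early genes (6.98 to 7.06).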

How the results depend on the processing

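Removal of the length and GC trend and leaving out title numbers were chosen after seeing the data. Against 1737 called genes (773 higher, 964 lower), fits without a filter, with a stricter one, with other scalings, variance models or library weights gave 1510 to 1935. Counts moved by over 1.5 times to 886 (395 higher, 491 lower) with a random effect for shared title number and diet, where the correlation of such embryos was 0.267, and to 298 (110 and 188) with such embryos averaged, which leaves 4 values per group. They moved to 91 (34 and 57) with the somatic covariate, whose own difference between diets had an exact permutation p of 0.0693. By the exact test they were 558 (267 and 291), all of them genes whose groups do not overlap. They moved to 2723 (1215 and 1508) at an adjusted p below 0.1 and to 444 (189 and 255) below 0.01. They were 729 (325 and 404) without title number 1 and 49 (9 and 40) without title number 4, with 8 embryos in each fit; the cause was not tested. Leaving out single embryos gave 808 (365 and 443) without supplied replicate 5 to 2315 (1034 and 1281) without supplied replicate 4, with 1133 (506 and 627) without supplied replicate 6. Of 24 lists 13 passed camera, 8 with the somatic covariate, 0 with an estimated correlation, 13 by fry and 11 to 15 without single embryos. For immediate early genes alone camera's direction turned from positive to negative while passing, at a median of -0.0754 against -0.0039 in the reported fit (adjusted p = 0.0228) without title number 4; the cause was not tested.

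Title number as a replicate block gave 2062 genes and 13 lists. The numbers were not taken to pair embryos, because deviations from the group means correlated between -0.23 and 0.24 over the 10 pairs with the same number in both groups, and 4 embryos correlated best with their own number. Over the named genes, 3205 values kept their direction and side of the threshold, 440 were no longer called and 62 became called. An offset of 10 on the linear scale was not run, because the scale could not be inverted, and surrogate variables were not run, because they need counts. Depth is unknown, and how far the scale limits fold changes of genes with low values was not measured.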

Other observations

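Basement membrane genes, the glycine cleavage genes, feedback genes of FGF and ERK signalling and ribosome biogenesis genes are described from lists drawn up after the largest changes had been seen, so neither their counts nor their tests are independent evidence. The tests of somatic cell share and developmental timing for the meiosis and pluripotency lists and the splits of averaged embryos were also chosen after the results were seen, as were removal of the length and GC trend and the test of length slopes by title number.

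Of 17 basement membrane genes, 9 were lower in withdrawn embryos, including the collagen IV genes Col4a1 (-0.98) and Col4a2 (-0.66), perlecan (Hspg2, -0.72), Pxdn (-0.59), which crosslinks collagen IV, and the laminin gene Lama1 (-0.59). The laminin receptor gene Itga6 (-0.47) was lower, whereas Nid2 (0.25) was higher. The list had an adjusted p = 0.0560 in camera with an estimated correlation. Of 8 genes of glycine cleavage and threonine breakdown, 5 were higher, Amt (0.61), Gldc (0.47), Tdh (0.29), Shmt1 (0.24) and Gcsh (0.24), with an adjusted p = 0.0560 with an estimated correlation. Tdh feeds glycine into this pathway in pluripotent mouse cells and is also on the pluripotency list.

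Targets and feedback inhibitors of FGF and ERK signalling were higher for 5 of 11 members, Etv5 (0.50), Etv4 (0.45), Spry4 (0.44), Dusp4 (0.40) and Dusp6 (0.35), with an adjusted p = 0.0722 with an estimated correlation. Ribosome biogenesis genes were higher for 11 of 20 members, with Tcof1 (0.55), Mybbp1a (0.49), Ruvbl2 (0.49) and Ncl (0.34) among them and an adjusted p = 0.0560 with an estimated correlation. No member of either list was lower.

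Lower meiosis and higher pluripotency genes in withdrawn embryos may reflect germ cells at an earlier stage at collection, as a hypothesis. Length and GC bias alone is argued against, since removal of that trend left 31 of 32 called members called. They kept a median of 0.967 of their fold change (95% bootstrap interval over genes 0.887 to 0.992). Both lists are of germ cell genes, which a change in somatic share alone would move the same way. Their mean log2 fold changes were -0.34 for meiosis (exact permutation p = 0.00866) and 0.28 for pluripotency (p = 0.00433), apart by 0.62 (p = 0.00433), so such a change is argued against as the whole cause. With the somatic marker mean as a covariate these members kept a median of 0.880 (0.848 to 0.949), but 3 of 32 stayed called while their median SE went from 0.09 to 0.11, and a part of somatic share in the size of either change stays open. Among supplied embryos alone, the slopes of 12370 other genes on the meiosis mean correlated across genes with minus the log2 fold change of the diet at 0.617, above 95% of the orders of the embryos (exact permutation p = 0.00556), and among withdrawn embryos at 0.552 (p = 0.0278), so diet and variation within groups share an axis. The test does not say whether that axis is age, pace of development or another source of variation, and diet as its cause stays open.

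Within each diet the meiosis and pluripotency means were opposed. Pearson's r was -0.936 in supplied (exact permutation p = 0.0153, adjusted 0.0153) and -0.993 in withdrawn embryos (p = 0.00139, adjusted 0.00278), n = 6 each, and Spearman's rho was -1 in both (exact permutation p = 0.00278). Without the 2 embryos farthest from the median r was -0.880 and -0.982. These 2 relations were the family tested. With the meiosis mean as a covariate limma called 0 genes, with 705 at an unadjusted p below 0.05. Sycp1 was at -0.57 (adjusted p = 0.0638), Col4a1 at -0.48 and Igf2 at -0.46 (adjusted p = 0.838). Nearer to none were Uhrf1 (-0.17), Apoe (0.18), Pou5f1 (0.07) and Hmgn5 (-0.05), and Stra8 turned to 0.16. Sycp1 and Stra8 are themselves part of the meiosis mean. No other tool was run with that covariate, which correlated with the diet at -0.772, so such a fit removes much of the diet difference itself.

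The basement membrane decrease could come from fewer somatic cells in the sorted fraction, whose markers were lower. With the somatic marker mean as a covariate the median fold change of the 9 lower genes was 0.822 of its size (95% bootstrap interval 0.586 to 0.911), and 5 stayed called while their median SE went from 0.10 to 0.12. The median lay above 0.8, which the rule set beforehand took to argue against a lower somatic share. That rule named the median alone, and the interval of the median spans the bound. Most of the markers also have low values. A lower somatic share and a change in germ cells therefore cannot be told apart here for these genes. Length and GC bias alone is argued against, since 9 of 9 stayed called after its removal, at a median of 0.848 of their fold change (0.807 to 0.921). Both intervals resample genes, which are not independent and were chosen as called, and leave out the spread between embryos.

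Across genes, which are not independent, log2 fold change and transcript length had a Spearman's rho of -0.248, and medians went from 0.03 in the decile of shortest transcripts to -0.07 in that of the longest. The length slope per library was 0.02 ± 0.02 in supplied and -0.02 ± 0.03 in withdrawn embryos (SD, n = 6, exact permutation p = 0.0649). Within diets the slope of title number 1, singled out after the slopes were seen, differed from that of the others over 225 arrangements (exact permutation p = 0.0356). With the trend removed 1730 genes were called, 1361 of them among the 1737.

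Of 461 X-linked genes 22 were higher and 76 lower. Their median log2 fold change was lower than that of autosomal genes (difference -0.0379, 95% bootstrap interval over genes -0.0521 to -0.0233). Camera gave p = 0.00254, and p = 0.0481 with an estimated correlation, and the mean of X-linked minus autosomal genes per embryo was -0.27 ± 0.02 in supplied and -0.32 ± 0.02 in withdrawn embryos (exact permutation p = 0.00433). Both camera tests met the criterion set beforehand for a shift of the whole chromosome, a p below 0.05. The difference also lay within the bound of 0.05 set beforehand for no shift, with an interval that reaches beyond it, so these values do not decide for or against one.

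In 100 of the 462 splits of the 12 embryos into groups of 6, the real split included, 1 gave as many called genes as the real count of 1737, and the highest other was 1729. For genes higher, 2 splits reached the real 773 (highest other 947), for genes lower 1 reached 964 (highest other 947), and for lists 2 reached 13 (highest other 14). The split with 14 lists called 0 genes, as did a split that exchanged 3 embryos per group and passed 10 lists. Camera at the preset correlation thus passed lists under other groupings too, and a pass alone is weak evidence for the diet. A split has no direction, so the larger of its higher and lower counts was taken. If the 12 embryos are independent, these shares make chance assignment to groups unlikely. They do not exclude it, since only 100 splits were drawn, of which 8 exchanged 1 embryo per group. Embryos that share title number and diet are perhaps siblings, which single-embryo splits ignore. With such embryos averaged, 2 of the 35 splits of 4 values against 4 gave as many genes as the real 298, and the highest other was 366, so chance cannot be excluded for that count. This other split exchanged supplied replicate 4 with withdrawn replicate 3. In the single-embryo splits, that with 1729 made the same exchange, and a split with 1175 exchanged supplied replicate 4 with withdrawn replicate 1. The 97 other splits called at most 2 genes. In an earlier draw of 100 splits the highest other count was far lower, and the draw with the higher one is given here.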
